A study of Mus musculus with 6 samples.

How the data were processed

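RNA of EML cells was sequenced in 6 libraries. EML is a mouse progenitor line from bone marrow that grows in stem cell factor, and KAI1 is the protein of the gene Cd82. Per the labels, the 6 libraries fell into 4 groups: the knockdown control and the KAI1 knockdown with 2 libraries each, and the overexpression control and the KAI1 overexpression with 1 library each. The labels name total RNA and the series design names mRNA levels measured on the Illumina GAIIx; whether RNA with a poly(A) tail was selected is not given in the sources used here. The means of knockdown and overexpression, the species of the introduced KAI1 sequence and the strandedness of the libraries are also not given in the sources used here. The labels call the cell type basophil, the tissue bone marrow and the strain BDF1. They number the libraries of the knockdown arm as replicates and do not state separate cultures.

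The authors deposited, for each library, a table of RPKM per transcript entry, that is reads relative to transcript length and to the number of mapped reads, per the file headers. The submitters' processing notes name the mouse build mm9, TopHat2 2.0.9, Bowtie and Cufflinks, with no version for the last pair and no settings. The design took the unit to be FPKM from the named tools; the headers say RPKM, and the same tests were used, since both are values relative to length and depth. Each table held 23170 entries keyed by RefSeq accession and locus. An accession and locus occurred again in 24 entries, of which 20 had identical values, and 23146 entries were used. The reference annotation was of another mouse build than mm9, so it served for names only and no coordinate was taken from it. A RefSeq table gave the symbol of 22840 entries and a GENCODE table that of 125, while 181 stayed without a symbol, 150 carried more than 1 symbol and 170 symbols stood on more than 1 entry. Coordinates are those of the deposited tables on mm9, with starts moved to count from 1, since end minus start equalled the stated gene length in 8124 entries and end minus start plus 1 in 523. For many small RNAs the deposited span is that of the host gene.

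A group of 672 small RNA entries was set apart by a span under 300 bp or by a small RNA class in the annotation. One entry without a symbol, on chromosome 17 (39979942 to 39985774), was also put in this group by hand after its values were seen. This entry spans more than 300 bp. It was listed at 0 in KAI1 knockdown replicate 2 and in the overexpression control and stood at 4448 RPKM or more in every other library.

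The sequencing depth is not stated, and it was estimated from the values. Where reads are counted whole, low values of 1 gene in different libraries are whole multiples of what 1 read is worth, so their ratios give the relative depth. All 15 pairs of libraries gave relative depths that matched through any other library within 0.5%, and the procedure recovered 15 of 15 pairs in simulated data. Set to knockdown control replicate 1, the relative depth was 0.519 in knockdown control replicate 2, 0.673 and 1.02 in KAI1 knockdown replicates 1 and 2, 1.36 in the overexpression control and 1.03 in KAI1 overexpression. The reference library was estimated at about 19200000 reads over 468 entries, with quartiles of 18600000 and 19800000. Reads behind small RNA values were taken back from those steps, as the smallest whole counts that fit the values. Multiples of these counts would fit as well. For some small RNAs, such as Mir3060, the RPKM are far higher than the smallest counts would give over their length at the estimated depth. In 79 of 116 small RNA entries above 0 in at least 2 libraries, or 68.1%, the values were whole reads within 0.2%, against 8.6% after random jitter. Since whole reads could be had only for part of the entries, no count test was run.

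The knockdown was tested with limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), with a mean-variance trend, on the 10113 entries with a mean of at least 1 RPKM over the 4 libraries of the knockdown arm. Tests were two-sided, and p-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. Fold changes are on the log2(RPKM + 1) scale, which understates the change of low genes. As a description that needs no variance, genes were counted whose libraries of 1 group all lay at least 2-fold above those of the other. The overexpression comparison has 1 library on each side and no test. It covered the 9936 entries with a mean of at least 1 RPKM over both libraries, by a size rule of at least 2-fold on the RPKM + 1 scale. Knockdown and overexpression changes were compared across the 10112 entries with a mean of at least 1 RPKM over all 6 libraries.

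The design fixed 23 gene lists: CDK inhibitors, TGF-beta ligands with receptors and Smads, TGF-beta response genes, G1/S and DNA replication, G2/M and mitosis, stem and progenitor, erythroid, megakaryocyte, neutrophil and monocyte, mast cell and basophil, lymphoid, macrophage and dendritic cell, stromal and fibroblast, tetraspanins other than Cd82, integrins and adhesion, interferon-stimulated, p53 targets, immediate early, cholesterol synthesis, hypoxia and glycolysis, unfolded protein and amino acid response, ribosomal proteins, and replication-dependent histones. Of their members, 460 were matched and 5 were not (Hba-a1, Ahsp, Cd68, Mx1 and Hist2h2aa1). Hmgcs1 matched only an unplaced locus listed at 0 in every library and counts as not measured. In the knockdown, 20 lists with at least 5 tested members were tested with camera of limma at a preset correlation of 0.01, and beside it with an estimated correlation and with fry. In the overexpression, the median log2 ratio of each of 21 lists was placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of those libraries.

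Named genes followed a rule. It takes Cd82 and Ackr1; in the knockdown, 10 genes in each direction among those past the threshold, filled up by smallest p where fewer passed; in the overexpression, the 10 largest ratios in each direction; genes of opposite direction in both comparisons; and list members as examples. Because small RNAs filled much of this choice, 10 genes in each direction that are not small RNAs were added after the values were seen.

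On simulated values for the knockdown comparison with 200 changed genes among 10113, the test recovered 0% of genes changed by 1 log2 unit, 14% at 2, 72% at 3 and 88% at 4, with 2 false calls, when the simulated spread was that observed in both groups. With the spread of the knockdown pair alone it recovered 62%, 96%, 100% and 100%, with 8 false calls. The changed genes were drawn from genes of higher level that are not small RNAs, with the same spread in every library. These shares therefore do not cover low genes, or a spread that is wider in the controls than in the knockdown. At the preset correlation the list test called 0 lists before a simulated shift and 1 after it. The simulated genes were drawn independently, so this does not show how often lists of correlated genes are called falsely. What the test with an estimated correlation can recover was not checked by simulation. In the knockdown data the estimated correlation of the lists that passed ranged from 0.037 (unfolded protein list) to 0.91 (G2/M), against the preset 0.01.

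The choices above, apart from the small RNA group, the matching of entries to names, the estimates of depth and of whole reads with their tolerances, and the added genes, were made before the data were examined, as were the alternatives: pseudocounts of 0.1 and 5, no filter and a mean of at least 5 RPKM, rescaling by a trimmed mean of M-values or by the median ratio, quantile normalization, limma without the trend or with its robust option, an adjusted p of 0.1, a ratio of at least 3, the replicate number as a block, and each library of the knockdown arm left out in turn. Leaving out the small RNAs, alone or together with knockdown control replicate 1, was added after seeing the data. Results of some single genes are not reported here. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared the tables and drew the plots.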

Results

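The series measured RNA in EML cells, a mouse haematopoietic progenitor line from bone marrow that can give erythroid, myeloid and mast lineages and is kept in stem cell factor. It asked what loss and gain of KAI1 do to mRNA levels. KAI1 is a membrane protein of the tetraspanin family, encoded by Cd82. Libraries came from a knockdown control (n = 2), a KAI1 knockdown (n = 2), an overexpression control (n = 1) and a KAI1 overexpression (n = 1), and their values are the authors' RPKM. The depth estimated from the values was about 19200000 and 9980000 reads in the knockdown controls, 12900000 and 19600000 in the KAI1 knockdown, 26100000 in the overexpression control and 19700000 in the KAI1 overexpression. The labels do not state separate cultures, so p-values measure only the spread between these samples, which may be technical.

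Cd82, the targeted gene (chromosome 2, 93259259 to 93310031 on mm9), stood at 43.9 and 13.8 RPKM in the knockdown controls and at 7.65 and 6.91 RPKM in the KAI1 knockdown. The means were 28.8 ± 21.3 (SD, n = 2) and 7.28 ± 0.525 (SD, n = 2), and both knockdown libraries lay below both controls. In the overexpression arm Cd82 stood at 11.9 RPKM in the control and 15.2 RPKM in the KAI1 overexpression, 1.26-fold higher on the RPKM + 1 scale. Ackr1 (chromosome 1, 175262017 to 175263634), which encodes the KAI1-binding chemokine receptor DARC, stood at 2.95 RPKM in knockdown control replicate 1 and 0.151 RPKM in KAI1 knockdown replicate 1 and was listed at 0 in the other libraries. The knockdown difference of Cd82 was -1.64 on the log2 scale (SE 0.58) and did not pass limma's test (adjusted p = 0.83). It was -0.84 without control replicate 1 (adjusted p = 0.406) and -2.44 without control replicate 2, where it passed (adjusted p = 0.0181) in a fit with 1 control library, whose spread within groups is that of the knockdown pair alone. Whether reads of the introduced sequence enter the overexpression value is not given in the sources used here.

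**Figure D1:**
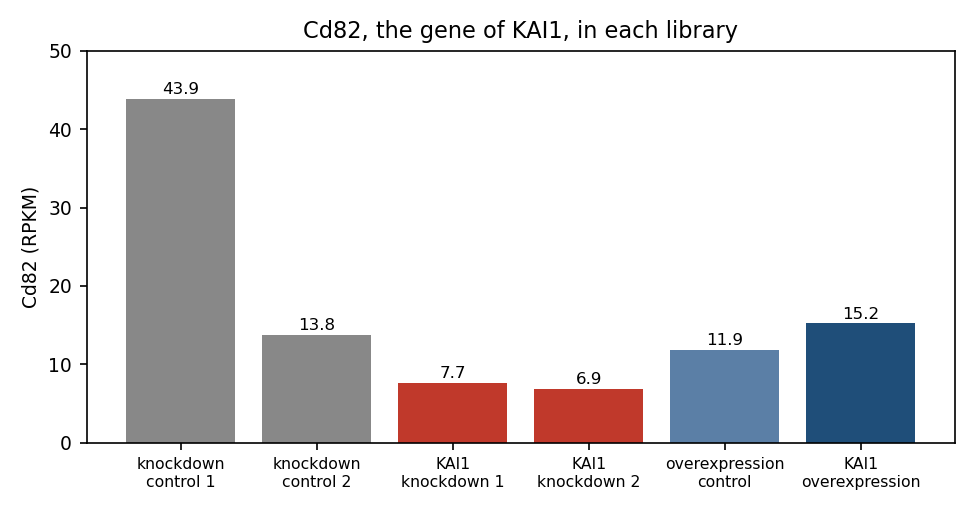
Cd82 in RPKM (vertical axis, from 0) in each of the 6 libraries, 1 bar for each library. The KAI1 knockdown libraries stand at 7.65 and 6.91 RPKM, below both knockdown controls at 43.9 and 13.8 RPKM, and the overexpression library at 15.2 RPKM stands above its control at 11.9 RPKM.

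In the knockdown, Pdia4, a disulfide isomerase of the endoplasmic reticulum, was among the genes that separated the groups most clearly, though it did not pass the test. It stood at 252 and 162 RPKM in the controls and at 18.9 and 24.5 RPKM in the knockdown (log2 difference -3.17, SE 0.34, adjusted p = 0.521). Of the 10113 genes tested, limma called 3, and all 3 were small RNAs with few estimated reads. The reads given are the smallest whole counts that fit the values, and the true counts may be higher. Mir3060 rose from 0 and 0 reads to 2 and 5 reads (adjusted p = 0.0373), Snord53 fell from 4 and 3 reads to 0 and 0 (adjusted p = 0.0198), and Snord61 fell from 4 and 1 reads to 0 and 0 (adjusted p = 0.0373). Among all other genes limma called 0, while 336 of all genes had an unadjusted p below 0.05, 183 higher and 153 lower. That is fewer genes than a cutoff of 0.05 would give by chance if no gene changed. In the simulation with the observed spread the test recovered 0% of genes changed by 1 log2 unit. The low number therefore does not show that no gene changed.

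Further genes of small p in the knockdown, none of them past the threshold (adjusted p from 0.0524 to 0.83), included several with a known role. Higher were Islr at 0 and 1.04 RPKM in the controls against 9.47 and 10.05 RPKM in the knockdown, and Pemt, which makes phosphatidylcholine, at 5.08 and 6.08 against 14.1 and 17.3 RPKM. Vgll4, a cofactor of TEAD transcription factors, stood at 4.81 and 4.98 against 10.5 and 11.5 RPKM, and the zinc finger gene Zfp385a at 1.79 and 4.57 against 13.9 and 13.8 RPKM. The histone genes H2bc1, H4c3 and H3c7 had log2 differences of 1.65, 1.53 and 1.51. Lower were Hint3, a nucleotide hydrolase, at 28.0 and 21.3 against 9.37 and 7.24 RPKM, and Eno1b at 154 and 318 against 8.61 and 16.5 RPKM. Eno1b is a near-identical copy of the glycolytic gene Eno1, which stood at 219 and 458 against 477 and 919 RPKM, so the split of reads between them is uncertain. The small RNAs Snord4a, Mir1932, Snord32a, Snord35b and Mir5098 were listed at 0 in both knockdown libraries, and Snora17 had 1 and 1 reads in the controls against 4 and 5 in the knockdown. Among genes added after their values were seen, Zfpm1, which encodes the GATA1 cofactor FOG1, stood at 14.2 and 15.3 against 29.6 and 42.3 RPKM, and Sar1b, a GTPase of vesicle export, at 20.8 and 22.8 against 9.42 and 9.37 RPKM.

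With quantile normalization 1 gene was called higher and 1 lower, as Snord61 missed the threshold (adjusted p = 0.0641). The calls moved with the controls. With a library left out its group has n = 1, so the spread within groups comes from the other pair alone, and such calls do not show that a gene would pass with a replicated group. Without control replicate 2 limma called 1045 genes, 409 higher and 636 lower, among them Islr, Zfp385a and Pdia4 with adjusted p from 0.0155 to 0.0176, and H3c7, Eno1b, H4c3, Hint3 and Pemt with adjusted p from 0.0284 to 0.0435. The small RNAs Snord4a, Mir1932, Snord32a, Snord35b and Mir5098 passed without either control (adjusted p from 0.00618 to 0.0128). Without control replicate 1 it called 16, 2 higher and 14 lower, of which 0 were other than small RNAs, and Mir3060 lost its call (adjusted p = 0.051). Only 8 genes were shared by these sets. Without KAI1 knockdown replicate 1 or 2 limma called 0 genes, with 88 and 58 at an unadjusted p below 0.05. By size alone, 52 genes had non-overlapping groups at least 2-fold apart, 19 higher and 33 lower, of which 14 and 24 were not small RNAs. With no size limit, both knockdown libraries lay above both controls in 21.5% of genes and below them in 17.0%, where chance gives 16.7% for each direction. Leaving out a library raised the number of 2-fold non-overlapping genes to 143 without control replicate 1, 1440 without control replicate 2, and 194 and 142 without knockdown replicates 1 and 2.

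The libraries were not equally alike. Knockdown control replicate 1 differed at least 2-fold from control replicate 2 in 2142 of 10112 genes, whereas control replicate 2 differed from KAI1 knockdown replicates 1 and 2 in 300 and 522 genes and these from each other in 257. Mast cell proteases were higher in control replicate 1 than in control replicate 2, with Mcpt4 at 9416 against 221 RPKM and Tpsb2 at 3379 against 45.1 RPKM, as was Kit, the stem cell factor receptor, at 437 against 83.3 RPKM. Erythroid and early myeloid genes were lower there, with the globin gene Hbb-bt at 57.5 against 2304 RPKM, the erythroid factor Klf1 at 0.949 against 27.0 RPKM, Mpo at 7.84 against 538 RPKM and Cd34 at 0.859 against 64.7 RPKM. Of the other libraries the KAI1 overexpression was nearest to control replicate 1, with 1365 genes at least 2-fold apart.

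Of the 20 lists tested in the knockdown, 7 passed camera at the preset correlation, 4 higher and 3 lower, and 0 passed with an estimated correlation, where the smallest unadjusted p was 0.119. By fry, which asks whether the genes of a list move on balance one way without comparing them with other genes, 0 passed, with a smallest unadjusted p of 0.0182 for the stem and progenitor list. Among all list members limma called 0 genes over all genes tested.

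Mast cell and basophil genes were lower in the knockdown by the list test, with a median of -1.29 over 19 genes (adjusted p = 1.94e-07; adjusted p = 0.81 with an estimated correlation). In 12 of the 19 both knockdown libraries lay below both controls and in 1 above. The protease Cpa3 stood at 6236 and 4110 RPKM in the controls and 2930 and 2355 RPKM in the knockdown, and Hdc, which makes histamine, at 902 and 150 against 32.7 and 64.2 RPKM. The cytokine gene Il4 stood at 78.5 and 30.3 against 10.3 and 3.74 RPKM, and Mcpt2 at 34429 and 8582 against 3726 and 3375 RPKM. Control replicate 1 lay 1.57 above control replicate 2 in the median of this list. The list median was -0.59 without control replicate 1 and -2.45 without control replicate 2.

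Replication-dependent histone genes, whose mRNAs are made in S phase and end without a poly(A) tail, were higher in the knockdown by the list test, with a median of 0.89 over 20 genes (adjusted p = 8.35e-08; adjusted p = 0.81 with an estimated correlation). Both knockdown libraries lay above both controls in 12 and below them in 1. H4c4 stood at 66.8 and 67.3 RPKM in the controls and 114 and 212 RPKM in the knockdown, H4c2 at 20.1 and 20.2 against 37.6 and 64.6 RPKM, and H2ac8 at 12.4 and 11.2 against 20.5 and 26.1 RPKM. The median was 0.88 without control replicate 1, 1.23 without knockdown replicate 1 and 0.52 without knockdown replicate 2. KAI1 knockdown replicate 2 and the overexpression control, the highest libraries in this list, were also those in which the entry without a symbol on chromosome 17 was listed at 0, against 4448 RPKM or more elsewhere. What this entry encodes was not established here, so it was not weighed in any explanation. Histone genes are near-identical copies, so the split of reads among them is uncertain.

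The lists of ribosomal, G1/S and G2/M genes were also higher by the preset test. Ribosomal protein genes had a median of 0.40 over 40 genes (adjusted p = 2.83e-05; adjusted p = 0.905 with an estimated correlation), with 20 above both controls and 0 below, for example Rps19 at 2188 and 2229 against 3330 and 3336 RPKM. G1/S and DNA replication genes had a median of 0.34 over 26 genes (adjusted p = 0.00231; adjusted p = 0.81 with an estimated correlation), with 11 above and 0 below, for example the replicative helicase gene Mcm5 at 42.8 and 68.0 against 96.5 and 94.7 RPKM and Uhrf1 at 32.7 and 36.3 against 55.0 and 60.3 RPKM. G2/M genes had a median of 0.23 over 22 genes (adjusted p = 0.02; adjusted p = 0.905 with an estimated correlation), with 7 above and 0 below, for example Plk1 at 30.3 and 36.1 against 45.1 and 60.5 RPKM. Control replicate 1 lay lower than control replicate 2 in all of these lists, with medians of -0.97, -0.32 and -0.64. Without it none of them passed (adjusted p = 0.298, 0.0833 and 0.27), the ribosomal and G2/M lists turned to the lower direction, and their medians were 0.062, 0.20 and -0.10; without control replicate 2 the medians were 0.76, 0.48 and 0.68. The G2/M list had a median of 0.35 without knockdown replicate 1, and of 0.12 without knockdown replicate 2, where it missed the threshold (adjusted p = 0.123).

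A pair of lists was lower besides the mast cell genes. Cholesterol synthesis genes had a median of -0.30 over 18 genes (adjusted p = 0.00449; adjusted p = 0.905 with an estimated correlation), with 6 below both controls and 0 above, for example Msmo1 at 64.7 and 82.3 against 40.0 and 55.7 RPKM and Insig1 at 36.1 and 55.3 against 24.7 and 33.2 RPKM. Genes of the unfolded protein and amino acid response had a median of -0.30 over 17 genes (adjusted p = 0.00673; adjusted p = 0.81 with an estimated correlation), with 6 below and 3 above. Its members included Pdia4, the transcription factor Atf4 at 658 and 535 against 348 and 382 RPKM and, in the other direction, the serine synthesis gene Phgdh at 82.6 and 139 against 206 and 191 RPKM. Neither passed without control replicate 2 (medians -0.38 and -0.069, adjusted p = 0.233 and 0.291), and the cholesterol list also missed the threshold without knockdown replicate 1 (median -0.16, adjusted p = 0.343). The unfolded protein list had a median of -0.46 without control replicate 1 and -0.48 without knockdown replicate 2.

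The remaining 13 lists did not pass. Erythroid genes had a median of 1.51 (adjusted p = 0.0716) that was -0.19 without control replicate 1, and they passed in the higher direction without control replicate 2 (adjusted p = 6.04e-06) and without knockdown replicate 1 or 2 (adjusted p = 0.0387 and 0.00782). With an estimated correlation they passed in none of these (adjusted p = 0.8586, 0.874 and 0.9478). Stem and progenitor genes had a median of 0.22 (adjusted p = 0.0914), and of 0.054 without control replicate 2. Immediate early genes had a median of -0.23 (adjusted p = 0.267) and passed in the lower direction without control replicate 2 (adjusted p = 0.013) or knockdown replicate 1 (adjusted p = 0.0357). With an estimated correlation they passed in neither (adjusted p = 0.8586 and 0.874). They turned to the higher direction without control replicate 1 (median 0.27, adjusted p = 0.5625). Hypoxia and glycolysis genes had a median of 0.0029 but a mean of -0.16 and a test in the lower direction (adjusted p = 0.792), and they passed in that direction without knockdown replicate 2 (adjusted p = 0.000519; adjusted p = 0.8168 with an estimated correlation). They turned to the higher direction without control replicate 2 (median 0.69, adjusted p = 0.624) and without knockdown replicate 1 (median 0.45, adjusted p = 0.0766). Tetraspanins other than Cd82 had a median of -0.0092 (adjusted p = 0.766), and of -0.52 without control replicate 2 (adjusted p = 0.316). Among them Cd53 stood at 69.3 and 23.8 against 13.9 and 11.9 RPKM and Cd81 at 73.8 and 35.5 against 1.15 and 24.0 RPKM. The adjusted p was 0.822 for TGF-beta ligands, for TGF-beta response genes and for interferon-stimulated genes, 0.792 for megakaryocyte, lymphoid and integrin genes, and 0.896 for p53 targets and for neutrophil and monocyte genes. The mean lay above 0 and the test lower in the neutrophil and monocyte list (median -0.012, mean 0.28) and for p53 targets (median -0.17, mean 0.0014). The median of the neutrophil and monocyte list was -0.27 without control replicate 1 (adjusted p = 0.0631) and 1.04 without control replicate 2 (adjusted p = 0.291). That of p53 targets was 0.36 and -0.55 (adjusted p = 0.0833 and 0.255). The CDK inhibitor, stromal and macrophage lists had too few tested members. The CDK inhibitor Cdkn1a stood at 628 and 187 against 282 and 268 RPKM, and Cdkn1c lay at or below 0.11 RPKM in all 6 libraries.

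**Figure D2:**
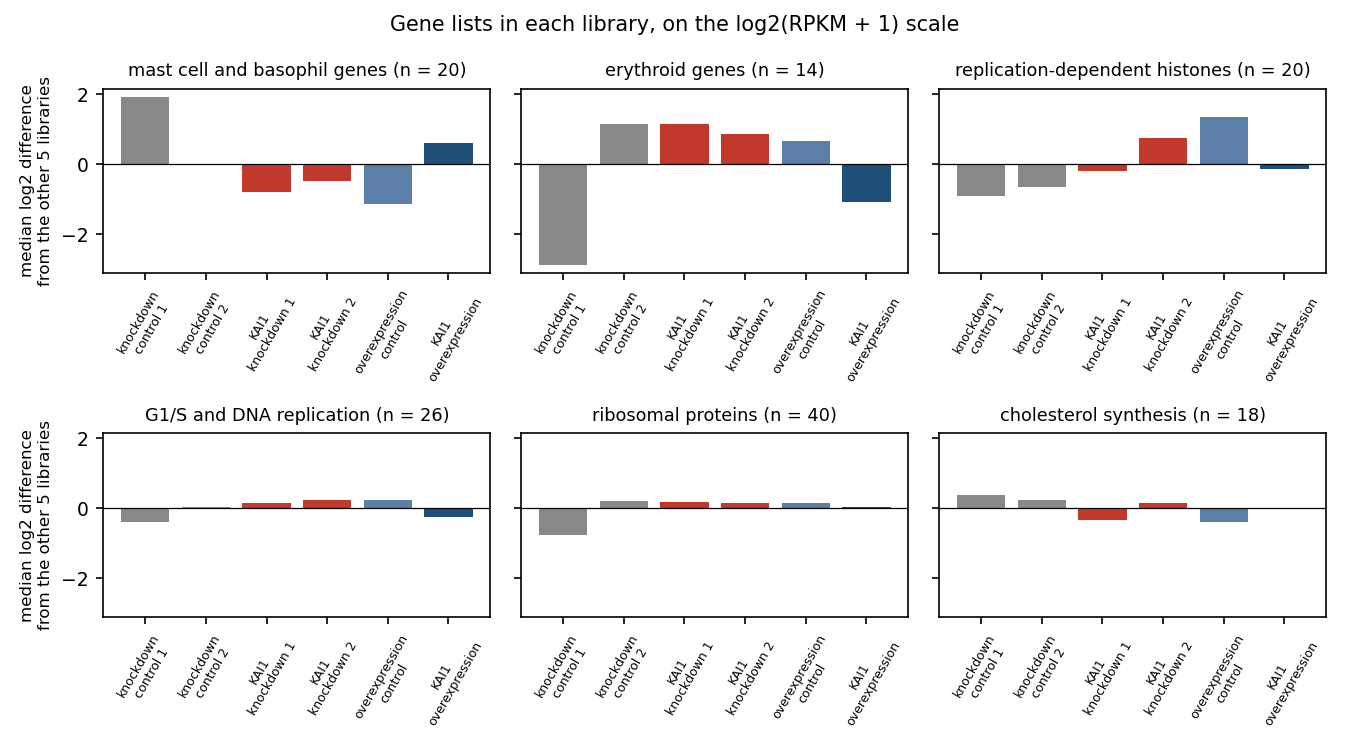
Median log2 difference of each library from the other 5 libraries (vertical axis, log2(RPKM + 1) scale) for 6 gene lists, 1 bar for each library. Knockdown control replicate 1 stands at 1.91 in mast cell and basophil genes and -2.87 in erythroid genes, and KAI1 knockdown replicate 2 and the overexpression control stand highest in histone genes, at 0.76 and 1.34.

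In the overexpression arm mast cell and basophil genes were higher and erythroid genes lower in the KAI1 overexpression library than in its control, each compared in 1 library against 1 and without a test. Of 19 measured mast cell and basophil genes, 14 were at least 2-fold higher and 0 at least 2-fold lower, with a median log2 ratio of 1.65. The granule protease genes Mcpt8 went from 491 to 3908 RPKM, Gzmb from 223 to 2775 RPKM, Cma1 from 879 to 8629 RPKM and Tpsb2 from 7.72 to 303 RPKM. Of 12 erythroid genes, 9 were at least 2-fold lower, with a median of -1.70: Klf1 went from 18.7 to 0.533 RPKM and the globin gene Hbb-bs from 200 to 22.4 RPKM. Histone genes were also lower, 13 of 20 by at least 2-fold with a median of -1.34, for example H4c4 from 257 to 96.6 RPKM and H2ac8 from 67.5 to 17.8 RPKM. Genes of connective tissue were detected in both libraries of this arm, with Acta2 at 6.38 and 5.47 RPKM and Timp1 at 6.14 and 5.25 RPKM in the control and the KAI1 overexpression, against at most 0.228 RPKM for Acta2 and 0 for Timp1 in the knockdown arm.

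By size, 489 of 9936 genes were at least 2-fold higher and 518 at least 2-fold lower in the KAI1 overexpression library, of which 458 and 470 were not small RNAs. The largest ratios were mainly of small RNAs listed at 0 in 1 of these libraries. Listed at 0 in the control were Snord69, Snord34, Snord4a, Snord53, Mir1982, Mir376b, Mir3074-1 and Mir2861, together with the entry without a symbol on chromosome 17. Listed at 0 in the KAI1 overexpression were Snord65, Snord38a, Snord61, Snord91a, Snord19, Snord58b, Mir142, Snord111, Mir144 and Mir451a. The remaining gene of this choice was Akr1c12, an aldo-keto reductase, at 2.11 against 287 RPKM. Of genes added after their values were seen, the higher ones included the chemokine gene Ccl4 at 0.548 against 68.8 RPKM and the serotonin transporter gene Slc6a4 at 5.65 against 172 RPKM. Also among them were the neighbouring receptor genes Lilr4b and Lilrb4a at 1.74 against 123 RPKM and 3.42 against 180 RPKM. Pea15a stood at 0.267 against 56.4 RPKM. The lower ones included the embryonic globin gene Hbb-bh1 at 218 against 1.51 RPKM, the carbonic anhydrase gene Car1 at 34.0 against 0.145 RPKM, the transcription factor gene Tcf7 at 83.3 against 0.912 RPKM and the platelet glycoprotein gene Gp9 at 29.8 against 0.467 RPKM.

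Among 10000 matched random lists, 10 of the 21 lists in the overexpression comparison lay near an end, among the outermost 5% of both ends together. The random genes were drawn independently of each other. Lists whose genes move together can therefore reach an end more often than 5% between any pair of libraries. Mast cell and basophil genes stood at the percentile 100 and cholesterol synthesis genes, with a median of 0.30, at 99.1, though at 95.77 to 97.44 with a pseudocount of 5 or another filter; Lss went from 19.9 to 35.9 RPKM. At the percentile 0 stood erythroid genes, histones, immediate early genes (median -0.83, with Zfp36 from 40.0 to 6.81 RPKM), stem and progenitor genes (median -0.49, with Cd34 from 66.4 to 15.9 RPKM) and G1/S genes (median -0.40, with Ccnd1 from 15.7 to 3.33 RPKM). Hypoxia genes stood at 0.07 (median -0.35), p53 targets at 0.14 (median -0.50) and integrins at 0.24 (median -0.38). The other 11 lay further in: TGF-beta ligands at 83.4, TGF-beta response genes at 42.2, CDK inhibitors at 9.64, G2/M genes at 45.8, megakaryocyte genes at 5.02, neutrophil and monocyte genes at 94.0, stromal genes at 12.3, tetraspanins at 34.7, interferon-stimulated genes at 47.6, the unfolded protein list at 69.7 and ribosomal proteins at 18.7. Lymphoid and macrophage lists had fewer than 5 measured members.

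Set side by side, genes higher in the knockdown tended to be lower in the overexpression library. Clec10a, a lectin receptor, stood at 553 and 6.99 RPKM in the knockdown controls, 0.75 and 0.609 RPKM in the knockdown, 0.503 RPKM in the overexpression control and 51.4 RPKM in the KAI1 overexpression. The serotonin synthesis gene Tph1 stood at 266 and 10.4, then 1.43 and 3.397, then 0.917 and 41.2 RPKM, and Cd200r3, a receptor of basophils and mast cells, at 54.6 and 5.998, then 1.01 and 2.46, then 0.0997 and 10.3 RPKM. In the opposite direction Islr went from 11.3 to 0.30 RPKM and Zfp385a from 19.9 to 5.12 RPKM with overexpression. Other genes at least 2-fold opposite included Spink2, Lpxn, Pilra, Snord53, Snord4a, Snord32a, Snord35b and the histone genes H2bc1, H4c3 and H3c7. In the knockdown, Clec10a, Tph1, Cd200r3, Spink2, Lpxn and Pilra passed only without control replicate 2 (adjusted p from 0.00618 to 0.0247), against 1 control library. Across 10112 genes, which are not independent replicates, Pearson's r between the knockdown and overexpression changes was -0.388 and Spearman's rho -0.42, and the comparisons share no library. Of the 3 genes called in the knockdown 1 was opposite in the overexpression (33.3%), against 62.5% of all genes higher in the knockdown and 64.9% of all genes lower. Without control replicate 1 r was -0.138 and rho -0.176, and 8 of 16 calls were opposite; without control replicate 2 r was -0.409, and 863 of 1045 calls (82.6%) were opposite. The difference of control replicate 1 from control replicate 2 had itself an r of 0.316 with the overexpression change.

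**Figure D3:**
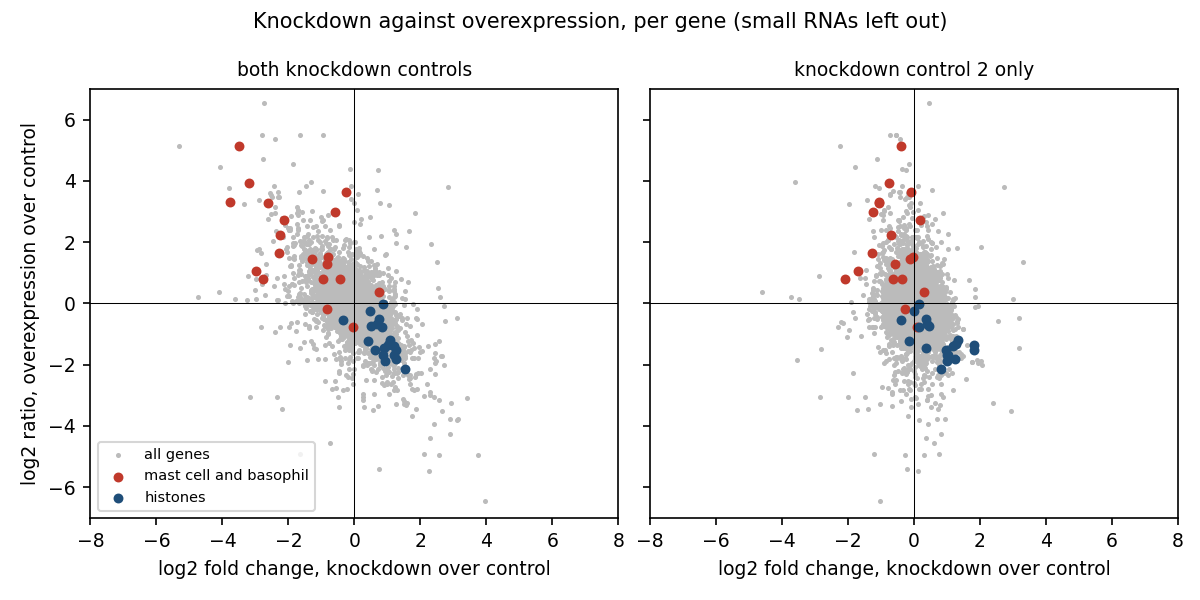
Log2 fold change in the knockdown (horizontal axis) against the log2 ratio in the overexpression (vertical axis), 1 point for each gene without small RNAs, with mast cell and basophil genes in red and histone genes in blue. The points are the genes tested in the knockdown. Over the genes with a mean of at least 1 RPKM over all 6 libraries, a set that is not identical, r is -0.517 with both controls (left). With control replicate 2 alone (right) it is -0.183.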

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

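The tests without small RNAs, alone or together with knockdown control replicate 1, were chosen only after the results were seen. The number of genes called in the knockdown was 3; it was 5 with a pseudocount of 0.1, 0 with a pseudocount of 5, 0 with no filter on low values, 0 without small RNAs (by construction, as all calls were small RNAs) and 0 without these and control replicate 1, with 341, 334, 683, 336 and 1533 genes at an unadjusted p below 0.05. Leaving out each library gave 0 to 1045. Cd82 in the knockdown ranged from -2.44 to -0.837 with a library left out and passed in 1 case, against 1 control library, and with all libraries it passed under none of the alternatives run for it, which did not include the filters. The 7 lists stayed the same under the other pseudocounts and filters and without small RNAs. Their number was 4 without control replicate 1, 5 without this and small RNAs, where neutrophil and monocyte genes passed in the lower direction (adjusted p = 0.0448; adjusted p = 0.8984 with an estimated correlation), 7 without control replicate 2 and 8 without either knockdown replicate. Without control replicate 2 erythroid and immediate early genes replaced the cholesterol and unfolded protein lists; without knockdown replicate 1 erythroid and immediate early genes came in and cholesterol genes dropped out, and without knockdown replicate 2 erythroid and hypoxia genes came in and G2/M genes dropped out. With an estimated correlation 0 lists passed under any alternative that kept all libraries, with a smallest adjusted p of 0.7809. Too few libraries were at hand to estimate correlations well, so this does not show that the lists were unchanged. The 52 non-overlapping genes became 98 with a pseudocount of 0.1, 24 with 5, 102 without small RNAs or control replicate 1, and 142 to 1440 with a library left out, where 1 library fewer eases the rule. In the overexpression, the 1007 genes at least 2-fold apart became 539 with a pseudocount of 5, 654 with a mean of at least 5 RPKM and 498 with a ratio of at least 3, as stricter rules must give fewer, and Cd82 went from 0.337 to 0.264 with a pseudocount of 5, which shrinks ratios. The lists near an end numbered 10 in every setting, but cholesterol genes, at the percentile 99.1, fell inside the limits with a pseudocount of 5 (97.2), no filter (97.44) and a mean of at least 5 RPKM (95.77). Neutrophil and monocyte genes took their place with a pseudocount of 5 (98.79) and a mean of at least 5 RPKM (99.54), and lymphoid genes with no filter (0.33). The correlation across genes of -0.388 became -0.517 without small RNAs, -0.183 without these and control replicate 1, and -0.409 to -0.138 with a library left out. The share of opposite calls, 33.3%, was 40% with a pseudocount of 0.1, 50% with a mean of at least 5 RPKM and 50% to 82.6% with a library left out; where 0 genes were called it could not be computed. Except where the construction is named, the cause was not tested. Rescaling by either rule and quantile normalization moved the median of all genes by less than 0.1 and left 7 lists; rescaling left 3 calls, and quantile normalization left 2, as Snord61 missed the threshold (adjusted p = 0.0641). With the replicate number as a block limma called 4 genes, 1 higher and 3 lower, and 9 lists, with erythroid and stem and progenitor genes added (none with an estimated correlation, adjusted p = 0.9036 or more), and Cd82 had an adjusted p of 0.999; deviations of same-numbered libraries had a correlation of -0.075, so the numbers are not shown to pair the samples. Of the values of single named genes, 481 stayed, 39 moved, 30 passed a threshold they had missed and 14 lost it. Some genes named for the overexpression changed direction in the knockdown without control replicate 1. Akr1c12 went from -2.74 to 0.45 on the log2 scale and Hbb-bh1 from 3.96 to -1.02. The 2 and 5 reads estimated for Mir3060, as smallest fitting counts, stand beside 156 and 257 RPKM. At depths of about 9980000 to 26100000 reads, so few reads over the length of a small RNA would give far lower RPKM. Either these counts are too low or the values do not rest on that length, which was not tested. The read numbers of small RNAs are therefore uncertain.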

Other observations

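Of the tests below, those on knockdown control replicate 1, on the histone genes and on depth in the overexpression arm were chosen only after the result was seen, the last of these in 3 successive forms; the test on connective tissue genes of a further list was written before its result.

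Some genes moved apart from the lists. Pdia4 was low in both the knockdown and the overexpression: it stood at 252 and 162 RPKM in the knockdown controls and 353 RPKM in the overexpression control, against 18.9, 24.5 and 41.9 RPKM in the KAI1 knockdown and KAI1 overexpression libraries. Dnajb9, a cochaperone of its list, was also lower in both, at 2.66 and 3.20 against 1.21 and 1.04 RPKM and at 2.19 against 0.904 RPKM, whereas the chaperone Hspa5 stood at 71.9 and 105 against 68.5 and 78.6 RPKM and at 92.9 against 120 RPKM. Zfpm1, the FOG1 gene, lay at 29.6 and 42.3 RPKM in the knockdown against 14.2 and 15.3 RPKM in its controls, and at 10.2 RPKM in the overexpression against 53.8 RPKM. In the knockdown none of these genes passed limma's test over all genes, and in the overexpression no test was made.

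Ccl4 and Osm, genes of secreted factors among those added after their values were seen, were highest in the overexpression library, without a test. Ccl4 stood at 68.8 RPKM there and at most at 2.98 RPKM elsewhere, and Osm, which encodes oncostatin M, stood at 32.8 RPKM and at most at 0.513 RPKM elsewhere. Akr1c12 stood at 287 RPKM and Akr1c13 at 441 RPKM in this library, and both were also high in knockdown control replicate 1, at 124 and 215 RPKM, against at most 2.11 and 18.8 RPKM in the other libraries. The members of this family are close copies, so their values are not independent.

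Knockdown control replicate 1 stood apart, rich in mast cell genes and poor in erythroid genes. Sequencing depth as the whole cause is argued against by 1875 genes at least 2-fold apart from KAI1 knockdown replicate 2, a library of nearly the same depth, when control replicate 2, at about 0.5 of it, differed from that library in 522. A minority of mast-lineage cells added to the culture is argued against by the erythroid genes, whose median was -3.50 against control replicate 2 with 11 of 14 below -1, since added cells leave most of the other RNA in place. A wrong label or another state of the culture cannot be told apart here, since the library's nearest neighbour, the KAI1 overexpression library at an r of 0.91 across genes, could come from either and the labels give no further date or batch. No biological explanation was tested, as both libraries carry the same group label.

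By the list test at the preset correlation histone genes were higher in the knockdown, though not with an estimated correlation (adjusted p = 0.81). They were lower in the overexpression, in 1 library against 1 and without a test. Their mRNAs lack a poly(A) tail, and so do Rpph1 and Rmrp, the RNAs of ribonuclease P and of its relative, whose median difference was 0.59 in the knockdown and -1.22 in the overexpression (Rpph1 stood at 104 and 74.9 against 120 and 169 RPKM, and at 337 against 171 RPKM; Rmrp at 481 and 213 against 437 and 463 RPKM, and at 1284 against 466 RPKM). In the knockdown this rests on these RNAs alone, and Rmrp lay highest in control replicate 1. Varying carry-over of such RNA may contribute. A larger share of cells in S phase may do so as well, since the G1/S list had medians of 0.48 and 0.20 against control replicates 1 and 2 alone and -0.40 in the overexpression. The lists did not move in step between the KAI1 knockdown replicates, each set against the other libraries. Histone medians were -0.20 and 0.76 in replicates 1 and 2, and G1/S medians 0.15 and 0.24. Carry-over and a larger share of cells in S phase both stay open, and an effect of KAI1 on either was not tested.

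Connective tissue genes were detected in both libraries of the overexpression arm. Pdgfrb, of the list in which this was seen, lay at 9.75 to 49.8 RPKM in all 6 libraries. Depth as the cause is argued against by the 7 genes of this list at 1 RPKM or more in any library: 6, all but Pdgfrb, were higher in the KAI1 overexpression library than in both knockdown control replicate 1 and KAI1 knockdown replicate 2, which have nearly its depth, where 24.2% of all genes at that level were. Libraries of equal depth should not differ so if depth were the cause; the genes are those in which the pattern was seen, so this does not test the pattern itself. Timp1 stood there at 5.25 RPKM against 0 in both, and Sparc at 2.80 RPKM against 0.139 and 0.0227 RPKM. RNA of stromal or fibroblast cells in that arm may be the source, as 11 of 20 genes of a further list of such markers (55%) were higher in both of its libraries than in each of the other 4, against 6.45% of all genes above 0 in any library, among them Fbln2 at 1.55 and 1.03 RPKM and Thy1 at 0.84 and 0.432 RPKM. These 11 lay at or below 1.55 RPKM and were 11 of the 15 members below 2 RPKM in every library, against 7.46% of all genes of that level, while the members above 2 RPKM in any library, Mmp2, Pcolce, Twist1, Loxl2 and Axl, did not follow: Mmp2 stood at 1.01 and 13.1 RPKM against up to 9.88 RPKM in the knockdown arm, and Twist1 at 4.18 and 0 against up to 2.93 RPKM. The source therefore rests on genes of low level. Expression by the EML cells of that arm themselves was not excluded.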
